A study of Mus musculus with 6 samples.

How the data were processed

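Gene expression was measured by poly(A)-selected, stranded mRNA sequencing in 6 libraries of GC-1 spg cells, an immortalised mouse cell line derived from type B spermatogonia. Per the labels, 3 libraries came from cells transfected to overexpress SNHG1, a small nucleolar RNA host gene that yields a long non-coding RNA, and 3 from cells that received the empty vector, all collected 24 hours after transfection. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical. Libraries were assigned to groups from their titles alone.

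The authors deposited 1 table of 57180 gene rows with whole-number counts and FPKM values for each library. Per the submitters' processing notes, HISAT2, SAMtools 1.3.1 and StringTie were used and the genome build was the human GRCh38, whereas all 57180 rows carry mouse Ensembl identifiers. The counting step, its strand setting and the build of the coordinates in the table are not given in the sources used here. Coordinates are therefore printed as the deposited table gives them, with no build named: of 51884 identifiers shared with the GENCODE M21 annotation of GRCm38, 2.69% had identical coordinates. The deposited counts have several properties of estimates. In 340 rows the count was exactly 1 in all 6 libraries, and 271 of these were snoRNA or miRNA genes. The authors scaled the deposited FPKM values by the total count of each library, because count divided by FPKM and total differed between libraries by at most 0.0698% within a gene. The gene length implied by that ratio exceeded the genomic span in 13.7% of 12373 rows with 50 or more counts, and was 20719 bp for Snhg1 against a span of 3011 bp. No column of per-sample values was left unused. Symbols were taken from the table, and the 525 rows without a symbol held 0.194% of the counts.

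Total counts ran from 15521900 to 21095427 per library, so 1 count stood for 0.047 to 0.064 CPM, where CPM is the count scaled to a library total of 1000000. A count of 0 allows up to 3 counts, which is 0.142 to 0.193 CPM. Such floors cover counting error only, since PCR copies are not independent molecules.

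The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM normalization, the default filterByExpr filter, group as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values were scaled by TMM factors, which ran from 0.9961 to 1.0046. Errors of log2 fold changes are standard errors from the fit, and errors of CPM values are standard deviations over 3 libraries. Gene lists were tested with the camera procedure of limma 3.58.1 on the moderated statistics, at a preset inter-gene correlation of 0.01 and with adjustment over the 27 lists with 5 or more tested members, and again with a correlation estimated for each list. Negative estimates were set to 0, and an estimate under 0.01 makes the second run less strict than the first. In all, 30 lists were fixed before the data were examined. They cover IL-17 and NF-kappaB signalling, interferon, stress and metabolic responses, the cell cycle, germ cell stages, other testicular and blood-derived cell types, and the surroundings of Snhg1.

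Genes named in the text followed a rule also fixed before the data were examined. It took Snhg1, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 20 counts, complete separation of the groups and an approved-style symbol, up to 3 members per direction of lists that passed or held 3 or more changed members, any single changed member of other lists, 9 IL-17 pathway genes, and Actb and Gapdh. Other genes, where named, were chosen after their values were seen, as were 5 gene families in the closing section.

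The pipeline was tested on simulated counts for this comparison, made from the means and dispersions of the 14605 tested genes and from the library sizes. Of these genes, 14432 passed the filter in the simulated counts. The test recovered 91% of 100 genes changed by 2-fold and 52% of 100 genes changed by 1.5-fold, and it called 9 of 14232 unchanged genes, which were 5.9% of its calls. That single data set was drawn from the kind of count model that edgeR fits, without trends of the libraries with GC content and length. The share of false calls in the real data may therefore differ. Lists of 20 genes raised by 1.5-fold had a p under 0.05 in 20 of 20 simulated data sets, against 0 of 20 for unchanged lists. The genes were simulated independently of each other, whereas the correlations estimated for the fixed lists reached 0.684. The simulation therefore does not give the rate of false passes for lists of correlated genes.

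Alternatives fixed before the data were examined were median-of-ratios size factors, total counts alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fold threshold, and for lists an estimated correlation and fry. An alternative filter meant for a table with normalized values only did not apply, since counts were present. A further 3 alternatives were chosen after seeing the data, namely offsets that remove each library's trend with GC content and transcript length (loess span 0.3), robust dispersions, and leaving out genes that differed by over 1 log2 unit within a group. GC content and length were taken from GENCODE M21 transcripts matched by identifier and were found for 97.5% of the tested genes. Figures were drawn with matplotlib 3.10.9.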

Results

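The series compared GC-1 spg cells labelled as overexpressing SNHG1 with cells carrying the empty vector, 24 hours after transfection, and its title places SNHG1 in the IL-17A signalling pathway. Each group held 3 libraries. Total counts were 19495464, 21058425 and 19204858 in the libraries labelled SNHG1 overexpression and 21095427, 15521900 and 18457861 in the vector libraries. The replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 11.55 to 18.28 over gene counts, so no library was counted as a copy of another. The first principal component held 32% of the variance and separated the groups. SNHG1 overexpression replicate 1 stood apart on the second component (19.2% of the variance), at 28.69 against -9.10 and -13.76 for the other replicates of its group, and its pairs with them had the highest chi-square values, 17.58 and 18.28.

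Snhg1 itself was measured first, because it checks the labels. Snhg1 (ENSMUSG00000108414, chromosome 19, 8700801 to 8703811 as the deposited table gives it, build not named, and annotated as a lncRNA) stood at 25.2 ± 1.19 CPM (SD, n = 3) in the libraries labelled overexpression and at 23.0 ± 2.64 CPM (SD, n = 3) in the vector libraries. The counts were 467, 555 and 487 against 464, 402 and 385. The log2 fold change was 0.14 ± 0.10 (SE), with a 95% interval of -0.095 to 0.366, and edgeR gave an adjusted p of 0.52. An increase of the counted mouse gene was therefore not detected, and the groups overlapped. Which sequence the construct carried is not given in the sources used here. Because Snhg1 does not separate the groups, they are called the labelled libraries and the vector libraries, and each direction below is that of the labels.

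Chemokine genes, C3 and Nos2 were among the largest increases in the labelled libraries. The neutrophil-attracting chemokines Cxcl5 and Cxcl1 rose by 3.76 ± 0.08 and 3.75 ± 0.14 on the log2 scale (SE, n = 3 per group), 13.5-fold in each case. Complement component C3 rose from 31.0 ± 1.66 to 665 ± 128 CPM (SD, n = 3), and the inducible nitric oxide synthase Nos2 from 1.92 ± 0.547 to 165 ± 40.2 CPM (SD, n = 3). Decreases were smaller, with log2 fold changes between -1.62 and -0.98 for the 10 largest that are named. On the deposited coordinates Cxcl5 (ENSMUSG00000029371) lies on chromosome 5 at 90907219 to 90909483, C3 (ENSMUSG00000024164) on chromosome 17 at 57510970 to 57535136 and Nos2 (ENSMUSG00000020826) on chromosome 11 at 78811613 to 78851080. Of 14605 genes tested, edgeR called 350 changed, 225 higher and 125 lower, and 334 of the 350 were protein coding. Increases of 2-fold or more numbered 65, and decreases of that size 11. All 350 separated the groups completely, as did 23.7% of all tested genes, where chance gives 10%. The count moved with every library left out, to 807, 162 and 176 without SNHG1 overexpression replicates 1, 2 and 3 and to 123, 151 and 143 without vector control replicates 1, 2 and 3, and DESeq2 called 691. All 350 kept their direction in each alternative that tested them, which complete separation of the groups nearly ensures, so it is no separate support. The median log2 fold change of all tested genes was 0.007.

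The other largest increases were in Saa3, Lcn2, Serpina3h, Bcl3, Ccl2 and Fas. Saa3, serum amyloid A3, had 230, 230 and 256 counts in the labelled libraries against 2, 0 and 3, with a log2 fold change of 6.95 ± 0.34 (SE). Lcn2, the siderophore-binding lipocalin 2, had 50, 77 and 41 counts against 4, 0 and 0, with a log2 fold change of 5.15 ± 0.64 (SE). Serpina3h, annotated as a transcribed pseudogene of a family of near-identical protease inhibitor genes, had 53, 46 and 56 counts against 0 in each vector library and was at least 47.6-fold higher, taking the floor of 3 counts over the vector group. Reads of such relatives were not told apart here, so which member of the family changed is uncertain. The NF-kappaB cofactor Bcl3, the monocyte chemokine Ccl2 and the death receptor Fas rose by 2.49 ± 0.18, 2.42 ± 0.10 and 2.32 ± 0.16 (log2, SE). These 10, the largest increases under the rule for named genes, kept their call in every alternative that tested them.

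**Figure D1:**
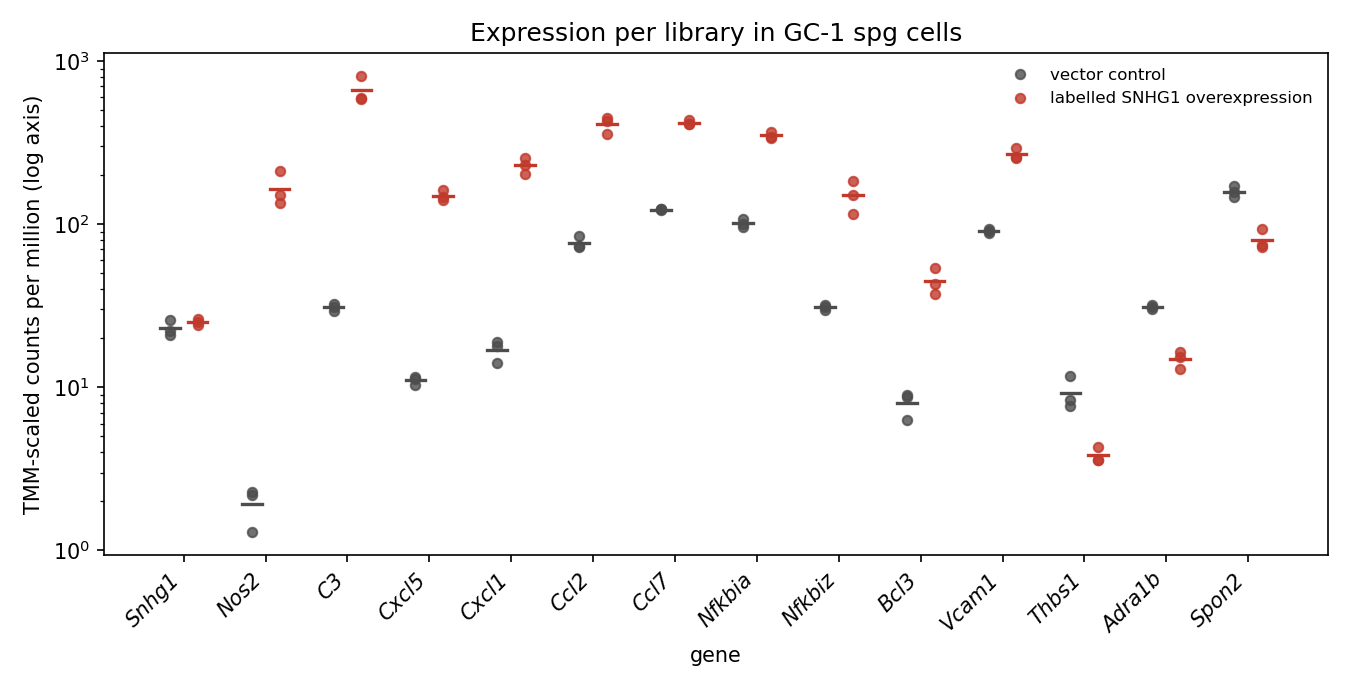
Expression of 14 genes in each library, as TMM-scaled CPM on a log axis. Points are libraries, 3 per group, and short lines are group means; Snhg1 overlaps between groups, at 25.2 and 23.0 CPM, while Cxcl5 stands at 150 CPM in the labelled libraries and 11.1 in the vector libraries.

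Most tested genes on the list of known IL-17 targets rose. Of 14 tested members, 10 rose and 0 fell, 12 when adjusted over the list alone, with a median log2 fold change of 1.89 (camera, adjusted p = 8.16e-22, and adjusted p = 1.3e-24 with an estimated correlation). Besides Cxcl5, Cxcl1, Ccl2 and Lcn2, the monocyte chemokine Ccl7 rose by 1.77 ± 0.05 and Nfkbiz, the nuclear cofactor that IL-17 induces, by 2.28 ± 0.15 (log2, SE, n = 3 per group). Il6 was at 2.75 ± 0.537 against 1.34 ± 0.522 CPM (SD, n = 3), which did not pass (edgeR, adjusted p = 0.145). Ptgs2 at -0.11 ± 0.05, Cebpb at 0.55 ± 0.12 and Lif at 0.44 ± 0.3 (log2, SE) did not pass either (edgeR, adjusted p = 0.328, 0.0567 and 0.491). Whether IL-17 or another stimulus raised the members that rose was not tested. Another 9 of the 24 listed genes had fewer than 10 counts in all libraries together. The summed CPM of 13 macrophage markers was 45.4 in the labelled and 34.5 in the vector libraries, a ratio of 1.32 (95% interval 1.19 to 1.46). Much of that rise lay in Cd14, at 24.4 against 14.4 CPM. A set of 10 blood cell genes without Cd14 had a ratio of 0.98 (95% interval 0.86 to 1.12).

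Genes of the IL-17 receptor and its adaptors mostly did not pass. Of 16 tested members 2 rose, 4 when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.326, with a median of -0.02 and a mean of 0.09). Traf3ip2, which encodes the receptor adaptor Act1, rose by 0.55 ± 0.07 and Traf2 by 0.67 ± 0.08 (log2, SE, n = 3 per group). The receptor chain Il17ra was at -0.05 ± 0.08, Il17rc at 0.25 ± 0.06 and the adaptor Traf6 at -0.14 ± 0.11, and none of these passed (edgeR, adjusted p = 0.788, 0.0868 and 0.544). Il17rc passed with DESeq2 (adjusted p = 0.0139) and with genes of over 1 log2 unit range within a group left out (adjusted p = 0.0389), in a range of 0.0139 to 0.267 over the alternatives. Leaving those genes out selects on small spread within groups, which can itself lower p-values, so that pass is no independent support. No count of the cytokine Il17a itself was found in any library, which allows up to 0.193 CPM in the shallowest.

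NF-kappaB pathway and target genes also rose. Of 19 tested members 10 rose, 15 when adjusted over the list alone, where 1 also fell, and the median log2 fold change was 0.92 (camera, adjusted p = 1.51e-18, and adjusted p = 8.12e-06 with an estimated correlation). The chemokine Ccl5 rose by 2.00 ± 0.07, the NF-kappaB inhibitor Nfkbia by 1.79 ± 0.07 and the adhesion molecule Vcam1 by 1.56 ± 0.07 (log2, SE, n = 3 per group). The cytokine genes Tnf and Il1b, named after their values were seen, had 0 counts in all libraries. Interferon response genes had 6 increases among 27 tested members, 14 when adjusted over the list alone, and a median of 0.29 (camera, adjusted p = 2.79e-10, but adjusted p = 0.0504 with an estimated correlation). Cxcl10 rose by 1.32 ± 0.11, the nucleic acid sensor Zbp1 by 1.23 ± 0.10 and the guanylate-binding protein Gbp2 by 0.56 ± 0.08 (log2, SE).

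**Figure D2:**
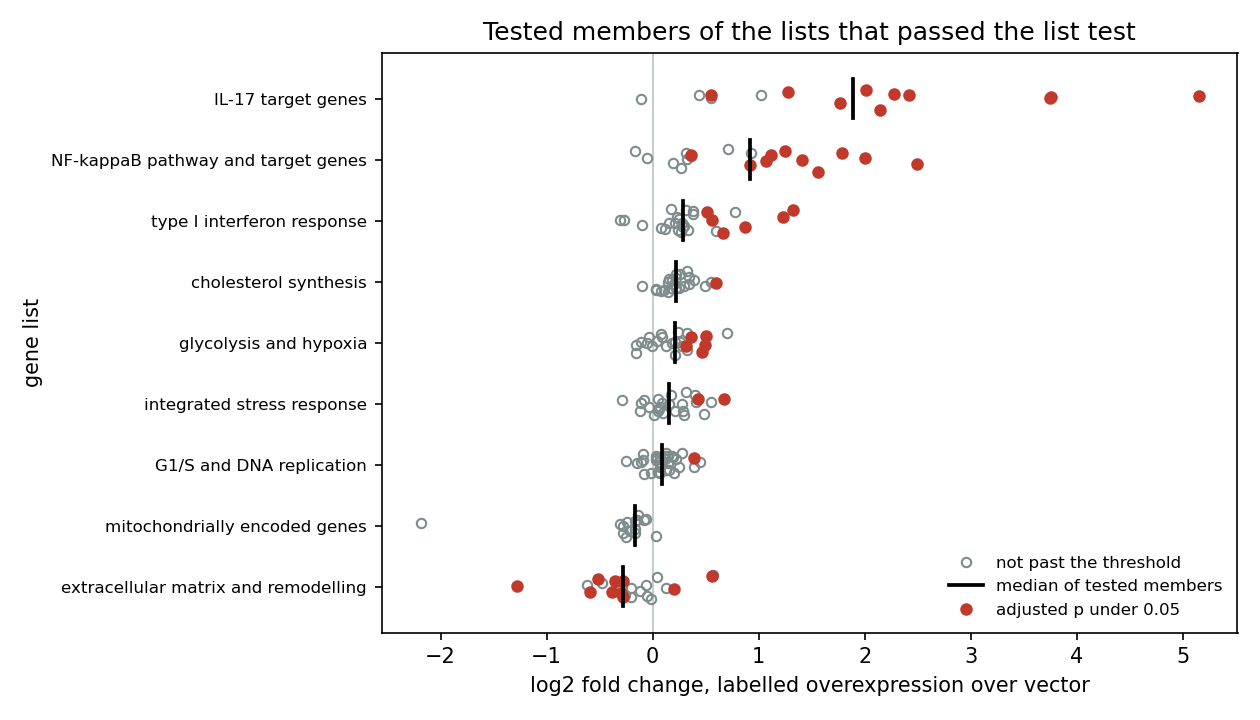
Log2 fold change, labelled over vector libraries, of the tested members of the 9 lists that passed the list test. Each point is a gene, filled where its adjusted p is under 0.05, and vertical lines are list medians; the medians of the IL-17 target and NF-kappaB lists lie at 1.89 and 0.92, and those of the other lists between -0.28 and 0.29.

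The list of glycolysis and hypoxia genes passed with small changes. Of 24 tested members 5 rose and 0 fell, 11 when adjusted over the list alone, with a median log2 fold change of 0.21 (camera, adjusted p = 3.22e-06, and adjusted p = 1.67e-06 with an estimated correlation). The estimate for this list was 0.004, so that run was also less strict than the preset of 0.01. The members that rose were Slc2a1, Pfkl, Ldha, Pgk1 and Pdk1, and the glycolytic enzymes Pfkl, Ldha and Pgk1 rose by 0.50 ± 0.07, 0.49 ± 0.07 and 0.36 ± 0.06 (log2, SE, n = 3 per group). The other 19 members did not pass, with log2 fold changes of -0.16 to 0.70. Cholesterol synthesis genes had 1 increase among 24 tested members, Mvd at 0.60 ± 0.10, and 12 when adjusted over the list alone (camera, adjusted p = 7.92e-08, but adjusted p = 0.23 with an estimated correlation). Integrated stress response genes had 2 increases among 25, Slc7a11 at 0.67 ± 0.11 and Shmt2 at 0.43 ± 0.09, and 4 when adjusted over the list alone (camera, adjusted p = 0.00299, but adjusted p = 0.363 with an estimated correlation). The calls of Slc7a11 and Shmt2 were lost in 8 and 12 alternatives. Genes of G1/S and DNA replication had 1 increase among 34, the kinase Cdk6 at 0.39 ± 0.06, and 2 when adjusted over the list alone (camera, adjusted p = 0.00658, but adjusted p = 0.654 with an estimated correlation and 0.278 without SNHG1 overexpression replicate 2, in a range of 1.05e-06 to 0.654 over the alternatives). Over 8194 genes of at least 20 CPM, the log2 fold change was also higher at higher GC content (Spearman rho 0.377 across genes, which are not independent replicates) and was lower for longer transcripts (rho -0.282).

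Extracellular matrix genes fell on balance. Of 25 tested members 8 fell and 2 rose, 12 and 3 when adjusted over the list alone, with a median log2 fold change of -0.28 (camera, adjusted p = 6.75e-06, but adjusted p = 0.104 with an estimated correlation). Col1a2, a chain of collagen I and the most abundant gene in these libraries, was at 13180 ± 96.8 CPM in the labelled libraries and 16170 ± 455 CPM in the vector libraries (SD, n = 3). Fibronectin Fn1 fell by 0.36 ± 0.05 and the collagen III chain Col3a1 by 0.52 ± 0.07, whereas the metalloprotease inhibitor Timp1 rose by 0.56 ± 0.08 and osteopontin Spp1 by 0.20 ± 0.04 (log2, SE). The call of Spp1 was lost in 12 alternatives, and those of Timp1, Fn1, Col3a1 and Col1a2 in 3, 3, 2 and 4. Of the 15 mitochondrially encoded genes, 0 passed the edgeR test over all genes, 12 had an unadjusted p under 0.05, DESeq2 called 5, and 12 were lower when adjusted over the list alone, with a median of -0.17 (camera, adjusted p = 1.93e-07, but adjusted p = 0.051 with an estimated correlation). All genes on the mitochondrial chromosome together took 2.41 to 2.63% of counts in the labelled libraries and 2.8 to 3.33% in the vector libraries. With GC and length trends removed the median of the 15 listed genes was -0.08, and mt-Atp6, the lowest at -2.19, differed by over 1 log2 unit between vector libraries. It stood at 3141.5, 3525.1 and 555.7 CPM in vector control replicates 1, 2 and 3. In the labelled libraries it stood at 522.7, 545.1 and 516.6 CPM. Part of the higher share in vector control replicates 1 and 2 is therefore due to mt-Atp6.

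The 10 largest named decreases included Thbs1, the matrix glycoprotein thrombospondin 1, at -1.28 ± 0.19, the alpha-1B adrenergic receptor Adra1b at -1.06 ± 0.10 and the secreted matrix protein Spon2 at -0.98 ± 0.11 (log2, SE, n = 3 per group). Ldb3, Mgat1, Acsbg1, Cdh26 and Zmat1 lay between -1.22 and -0.98. Tmed2 and Sgsh had the lowest values, -1.62 ± 0.25 and -1.45 ± 0.24, but their counts differed by over 1 log2 unit between libraries of a group. Ldb3, Adra1b and Spon2 kept their call in every alternative that tested them, and the other 7 lost it in at least 1.

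The remaining 21 lists did not pass or had fewer than 5 tested members, with adjusted p from 0.0933 to 0.986 for the 18 that were tested with camera. Of these, the G2/M and mitosis list (adjusted p = 0.307) passed without SNHG1 overexpression replicate 1 (adjusted p = 0.000693), without vector control replicate 1 (0.0216) and with GC and length trends removed (0.0229), in a range of 0.000693 to 0.953 over the alternatives. Among p53 target genes, Fas, Gadd45a at 0.57 ± 0.10 and Plk2 at 0.40 ± 0.06 rose, and Sesn1 at -0.42 ± 0.06 and Trp53inp1 at -0.36 ± 0.07 fell (log2, SE, n = 3 per group), with 7 increases and 3 decreases when adjusted over the list alone. Among immediate early genes, Ier3 rose by 1.07 ± 0.12 and Ier5 by 0.55 ± 0.08, and Ccn2 fell by 0.59 ± 0.11, with 5 increases and 2 decreases when adjusted over the list alone. Single members changed in 6 lists: Itga6 of the undifferentiated spermatogonia list (-0.45 ± 0.05), Spry1 of the ERK feedback list (-0.83 ± 0.12), Id2 of the TGF-beta and BMP list (-0.77 ± 0.15), Ctsl of the Sertoli cell list (0.58 ± 0.05), Pdgfra of the peritubular list (0.47 ± 0.07) and Cd14 of the macrophage list (0.76 ± 0.10). Adjusted over the list alone, the ERK list had 1 increase and 3 decreases, the TGF-beta and BMP list 1 and 1 and the macrophage list 2 and 0, and the others of the 6 kept their single member. Among 13 housekeeping genes Pgk1 passed, and 3 rose and 1 fell when adjusted over the list alone. Gapdh stood at 62.8 ± 4.07 against 50.5 ± 1.42 CPM and Actb at 1357 ± 500 against 1349 ± 397 CPM (SD, n = 3), and neither passed (edgeR, adjusted p = 0.0592 and 0.991). For Gapdh the adjusted p ran from 0.0118 with DESeq2 to 0.207 without vector control replicate 1 over the alternatives. No member passed edgeR in the other 11 lists, where 23 of 164 tested genes had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0. Adjusted over the list alone, 1 gene was lower in the meiosis list and 1 in the unfolded protein response list. These were differentiating spermatogonia, meiosis, G2/M and mitosis, apoptosis machinery, small nucleolar RNA host genes, genes beside Snhg1, the unfolded protein response, the oxidative stress response, replication-dependent histones, Leydig cell markers and endothelial markers.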

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

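The removal of GC and length trends, robust dispersions and the omission of 2-level genes (those differing by over 1 log2 unit within a group) were tried only after the data were seen. Snhg1 stayed below the threshold in every alternative, with a log2 fold change of 0.07 to 0.22. Against 350 changed genes, DESeq2 called 691, of which 336 were among the 350, and leaving out 2-level genes, which tests fewer genes, gave 577. That omission selects genes on small spread within groups, which can itself raise the count, so 577 is no independent support. The causes were not tested further. Requiring a 2-fold change left 76. With 1 library left out the count ran from 123 to 807: 807, 162 and 176 without SNHG1 overexpression replicates 1, 2 and 3, and 123, 151 and 143 without vector control replicates 1, 2 and 3. Fewer libraries remain in those fits, and the cause of the rise to 807 was not tested. Apart from the replicate block, every other alternative with all libraries gave 264 to 428. Against 9 changed lists, the estimated correlation left 3. These runs used the same statistics and differed only in the correlation. The 6 lists that no longer passed had estimates of 0.2 to 0.533 against the preset of 0.01. Their first adjusted p values therefore rest on that low preset. Without single libraries 8 to 12 lists passed. With fry 9 lists passed, but only 6 were among the first 9. With GC and length trends removed 10 passed, the first 9 among them. Lists that passed only in alternatives were housekeeping genes (no filter, adjusted p = 0.0274; without SNHG1 overexpression replicates 1 and 3, 0.0467 and 0.0416; fry, 0.026), the oxidative stress response (without SNHG1 overexpression replicate 1, 0.018), immediate early genes (without vector control replicate 3, 0.0426), Sertoli cell markers and p53 targets (fry, 0.00405 and 0.0305), and G2/M and mitosis in 3 settings. The planned filter for tables of normalized values alone was not run, since counts were present.

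The labels do not link replicate numbers to shared cultures. Correlations of deviations for libraries with the same number were -0.004, -0.03 and -0.021, so no pairing was detected, though these values cannot exclude one. With the replicate block 163 genes were called, 159 of them among the 350, and Actb was at -0.01; the block costs degrees of freedom, and the cause was not tested further.

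Of 55 named genes past the threshold, 26 kept their call in every alternative that tested them. A change of sign was seen in 0, which their complete separation of the groups nearly ensures. Calls were lost most often for Spp1 and Shmt2, in 12 alternatives each, Zmat1 in 11, and Id2 and Trp53inp1 in 10 each. Actb, not called at 0.0078, turned to -0.0093 with limma-voom, -0.0088 with log2(FPKM + 1), -0.009 with log2(FPKM + 0.1) and -0.04 with GC and length trends removed. Without single libraries it ran from -0.34 to 0.27, at -0.34 without SNHG1 overexpression replicate 2 and -0.12 and -0.11 without vector control replicates 1 and 3. Il17ra, not called, ran from -0.09 to 0.0046, the latter without SNHG1 overexpression replicate 3. The causes were not tested. Few counts limit the fold estimates, not the calls, of Lcn2 and Saa3, whose vector libraries held at most 4 counts each.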

Other observations

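The tests on depth, snoRNA genes, the construct, blood-derived cells, 2-level counts in inflammatory genes, simulated noise, a single odd library and overlapping genes were chosen after the results they bear on were seen, and so were the 5 gene families. The tests on GC and length, on splits of the libraries and on long exons were set before their results.

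Members of 5 further gene families passed the test, each family picked because some of its members stood out, so that no test of a family as a whole is given. Among 15 tested complement genes 6 rose and 1 fell, and 8 did not pass. Besides C3, C4b rose by 2.30 ± 0.27, and C1ra and C1s1, which encode proteases of the first complement complex, by 0.61 ± 0.07 and 0.58 ± 0.10, while Masp1 of the lectin pathway fell by 0.46 ± 0.08 (log2, SE). Of 15 TNF receptor family genes 6 rose, including Tnfrsf9 by 0.97 ± 0.08 and Tnfrsf1b by 0.56 ± 0.06. Of 18 genes of antigen processing 5 rose, led by the immunoproteasome subunit Psmb10 at 0.76 ± 0.06. Of 15 genes of the IL-6 family receptors and effectors 5 rose and 1 fell. The oncostatin M receptor Osmr rose from 49.0 to 150 CPM and Stat3 by 0.55 ± 0.06, while Lifr fell by 0.38 ± 0.07. Of 20 mesenchymal transcription factor genes 7 fell and 0 rose, among them Tbx18 at -0.49 ± 0.06 and Osr1 at -0.56 ± 0.11.

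Most listed germ line genes were at or near 0 counts in both groups. Of 24 genes of undifferentiated spermatogonia 12 had 0 counts in all 6 libraries, among them Zbtb16, Sall4 and Nanos2, and 17 had under 10 counts in all libraries together. Of 33 meiosis genes 13 had 0 counts and 21 under 10, and of 18 genes of differentiating spermatogonia 7, including Kit and Ddx4, had 0 counts and 10 under 10. The expression filter kept 6, 6 and 7 of these lists' members, and counts were found in every library for some, among them Foxo1 with 1367 to 1957, Ccnd2 with 4942 to 6882, Hspa2 with 464 to 626 and Prdm9, a histone methyltransferase of meiosis, with 200 to 328. Col1a2, Fn1 and Col1a1 were among the 10 most abundant genes, with 5165 ± 241 CPM for Col1a1 in the vector libraries (SD, n = 3). Absolute levels of this kind were not compared with another cell type.

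Among the 10 ways of splitting the 6 libraries into 3 and 3, 1, the real split, called 350 genes, and the highest of the other splits called 7. The splits are too few for a share under 0.05.

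The first pattern is that Snhg1 was not detectably higher in the labelled libraries. Too little depth to see an increase is argued against by the upper 95% bound of the fold, 1.29. Whether extra reads were counted under the 8 snoRNA genes inside Snhg1 stays open. A first criterion, the ratio of their summed CPM, gave 0.90 with an upper bound of 1.75. A second one, adopted only after that, was the upper 95% bound of the rise, taken as a difference in CPM. It was 7.5% of the vector Snhg1 level, while the bound of the ratio allows somewhat more. These sums cannot decide the question, because Gm25855, Gm22680, Gm22744, Gm23246 and Snord22 held exactly 1 count in every library. Such fixed counts may not register extra reads. Gm24452 held 1, 24 and 1 counts in the labelled libraries and 1, 30 and 1 in the vector libraries. Gm24453 held 15, 20 and 19 against 20, 10 and 18, and Gm25894 held 25, 27 and 18 against 29, 21 and 19. A construct of another sequence, such as the human gene, may leave no trace under the mouse gene, and with 0 rows of another organism in the table it cannot be told apart from a construct that was not expressed. A mislabelled or failed transfection also stays open and was not tested.

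The second pattern is the rise of inflammatory genes. Blood-derived cells in the labelled cultures are not fully excluded. The summed CPM of the whole list of 13 macrophage markers had a ratio of 1.32 (95% interval 1.19 to 1.46), from 34.5 to 45.4 CPM. Much of that rise lay in Cd14, at 24.4 against 14.4 CPM, or 0.76 ± 0.10 (log2, SE). A first set of 10 genes that left out Cd14 had a ratio of 0.98 with an upper bound of 1.12. Without Lyz2 its ratio was 0.83 (95% interval 0.62 to 1.1), and Lyz2 had 282, 312 and 321 counts against 304, 231 and 307. These sets argue against blood-derived cells for the genes they cover, while Cd14 goes the other way. With GC and length trends removed, 19 of the 20 changed members of the IL-17 target and NF-kappaB lists still passed, with a median log2 fold change of 1.75 against 1.78 before, and 1 of the 20, Lcn2, differed by over 1 log2 unit within a group. The last values argue against GC and length trends and 2-level counts as the whole cause, although a transfection or plasmid preparation that differed between the groups, such as its endotoxin content, is confounded with the labels and untested. An effect of SNHG1 on these genes is a hypothesis on the same footing, given the Snhg1 counts.

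The third pattern is that some genes differed widely within a group. They were picked by their range alone, which does not test for distinct levels. Of 8235 genes of at least 20 CPM, 156 differed by over 1 log2 unit within a group. That was 26 times the highest of 20 simulated data sets, which held 6. The simulation gave genes of like abundance the same replicate spread, so genes of wider spread alone could give an excess. No single library accounts for these genes, as the most frequent odd library was odd in 19.2% of them. Amd1 stood at 69.8, 68.6 and 7.8 CPM in the labelled libraries and 78.4, 75.5 and 6.5 CPM in the vector libraries. Pcdhgc3 was more graded, at 96.3, 183.9 and 659.7 CPM in the labelled libraries. A candidate explanation is the assignment of reads to gene models: 2-level genes overlapped another gene on the same strand more often (28.9% against 19.7%, odds ratio 1.65, 95% interval 1.12 to 2.41) with the 12 widest genes, which prompted the idea, left out, and with an odds ratio of 1.75 when they were kept, though most had no such overlap, and protein-coding genes of 5 to 20 CPM with a range over 1.5 log2 units, a separate set, more often had an exon of over 60% of the transcript (odds ratio 2.55, 95% interval 1.29 to 5.42), and no biological explanation was tested.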
